A study of Sinohyriopsis cumingii with 10 samples.

How the data were processed

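RNA of the pearl sac was sequenced in 10 libraries of the freshwater pearl mussel Sinohyriopsis (Hyriopsis) cumingii, 1 for each time after implantation: 0, 2, 6, 12, 24, 48 and 96 h and 7, 14 and 30 d. The labels do not say whether a library came from 1 mussel or from a pool, nor which tissue was taken at 0 h, so differences between animals and between times cannot be separated. Per the labels' protocols, the mussels were of similar size and were kept in aerated tanks on unicellular algae, and libraries were made from purified mRNA with random primers, size selection of the cDNA and PCR. The protocols name no molecular identifiers and no strand-marking step. The assembler, aligner, counting program and their versions are not given in the sources used here.

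Each deposited file lists contigs of an assembled transcriptome with a column of reads and a column of RPKM (reads scaled by contig length and library total), per the file headers. The deposited reads column was taken to hold expected counts, since its values are whole numbers except for 0.5, which stands in the same rows as an RPKM of 0 in every file and was therefore read as 0 reads; nothing else was rounded. RPKM values deposited by the authors were divided out with the reads and each library's own total to give contig lengths. The contig length obtained from reads, RPKM and total came out whole to within a relative distance of 5.6e-08, and 100% of the 211211 contigs with any reads in the undamaged files had the same length in each of these files that gave them reads. Lengths ran from 90 to 27255 bases with a median of 405. The files do not pair contigs with gene names, so 19 gene lists written in advance (immune receptors, antimicrobial effectors, stress proteins, shell matrix proteins, proliferation genes, markers of muscle, ciliated, nerve, germ and digestive cells, and others) matched no contig, and no list was tested. A contig is a piece of a transcript, and several contigs can belong to 1 gene, so counts of contigs are not counts of genes. Reads of near-identical copies or alleles can be split between contigs in a way these files do not show.

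In the 30 d file, 1 line holds a run of unreadable characters in the place of 166 contigs. These were left out of every library, which left 211508 of 211674 contigs. The RPKM values give the full 30 d total, 21263413 reads, of which 22413 (0.105%) belonged to the lost contigs. Totals ran from 20315910 to 24069268 reads per library. Intervals and floors cover counting error only, because each time had 1 library. They treat reads as independent, which PCR copies are not, so the intervals may be too narrow even for that. A count of 0 was given a floor of 3 reads.

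Library sizes were scaled with TMM factors (edgeR 4.0.16, R 4.3.3), and contigs were kept with filterByExpr on the trend design, which left 52894 contigs (25.0% of those readable). The factors ran from 0.594 at 6 h to 1.65 at 7 d, a 2.78-fold span. Relative to 0 h, TMM lowered values against plain CPM (reads scaled to a common library total) by 1.27 on the log2 scale at 7 d and by 1.07 at 48 h, and raised them by 0.20 at 6 h, so directions are given under both scalings where they differ.

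With 1 library per time, no pair of times can be tested. Time was therefore entered as log2(hours + 1) over all 10 libraries in edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05: once as a straight slope (8 residual degrees of freedom) and once as a linear and a quadratic term tested jointly (7 residual degrees of freedom), here called a smooth change. The spread in these tests is the scatter of libraries about the fitted curve. It holds differences between animals, tanks and libraries as well as real change that the curve cannot follow. Single times were set against 0 h as values only, with a fixed limit of 4-fold and, unless stated, a prior of 1 CPM added to both sides. Similarity was Spearman's correlation of log2(CPM + 1) over kept contigs, and principal components of the same values. These choices, and the rule to name at most 2 contigs of each direction with the lowest p of the slope test, were made before the data were examined. A fitted curve with its turning point between the 2nd and the 2nd last time of the fit was called a peak or a trough. Any other was called a rise or a fall. With all 10 libraries these limits were 2 h and 14 d. This grouping by shape, the measures of read concentration and detection, and the search for contigs of a single library were chosen after seeing the data.

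The tests were tried on simulated counts with the means, dispersions and library sizes of the 52894 kept contigs, 200 of them, drawn from those with a mean over 1 CPM, changed. For the slope test, 10.4% of 4-fold, 92.5% of 16-fold and 100% of 64-fold changes from 0 h to 30 d were called, with 7 false calls. For the smooth change, simulated as a peak or trough at the middle of the time scale, 8.96%, 95.5% and 100% of the same fold sizes were called, with 5 false calls. The dispersions of both simulations were a trend with abundance, estimated about the smooth curve. They leave out extra scatter of single contigs and, for the slope, real change off a straight line. The percentages may therefore overstate what the tests, above all the slope test, can call in the real libraries. Alternatives were DESeq2 size factors, total-count scaling, no filter, a filter of 5 CPM in 5 libraries, DESeq2 1.42.0, limma-voom and limma 3.58.1 on log2(RPKM + 1) with a minimum of 1 RPKM in 3 libraries, the rank of the time in place of its logarithm, and leaving out each time in turn. The smooth-change test was also run on 99 random orders of the libraries. Other values were computed with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.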

Results

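The series followed the formation of the pearl sac in the mussel Sinohyriopsis cumingii from 0 h to 30 d after implantation. Which tissue was taken at 0 h is not given by the labels. A pearl sac is the epithelial pouch that grows from grafted mantle tissue in a host mussel and lays down nacre. The title of the series places the interest in immune responses during its formation. Transcript levels were measured by RNA sequencing in 10 libraries, 1 per time, with totals between 20315910 reads at 96 h and 24069268 reads at 24 h. The transcripts are contigs of an assembly without gene names in the files, so the results below describe groups of contigs. No time had a replicate, and every comparison of a single time with 0 h is a comparison of 2 libraries without a p-value.

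The first question was how the reads were spread over the transcriptome as the sac formed. At 0 h the 70 most abundant contigs held 50% of all reads, and at 2 and 6 h the number was 77 and 64. It was 200 at 12 h, 167 at 24 h, 330 at 48 h, 263 at 96 h, 395 at 7 d, 249 at 14 d and 172 at 30 d. The 10 most abundant contigs of each library held 21.9% of the reads at 0 h, 23.0% at 6 h, 8.90% at 48 h, 10.2% at 7 d and 15.6% at 30 d. The 141 contigs with a mean of at least 1000 CPM (reads scaled to a common library total) held 56.5% of the reads at 0 h, 31.7% at 7 d and 43.8% at 30 d. Contigs of the middle class, with a mean of 10 to 100 CPM, numbered 6048 and held 12.3% of the reads at 0 h and 22.7% at 7 d. Contigs with at least 1 read numbered 128574 at 0 h (60.8% of the readable contigs), 169087 at 7 d (79.9%) and 147461 at 30 d (69.7%). With every library reduced to 20309026 reads, the numbers at 0 h and 7 d were 124227 and 166537.

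**Figure D1:**
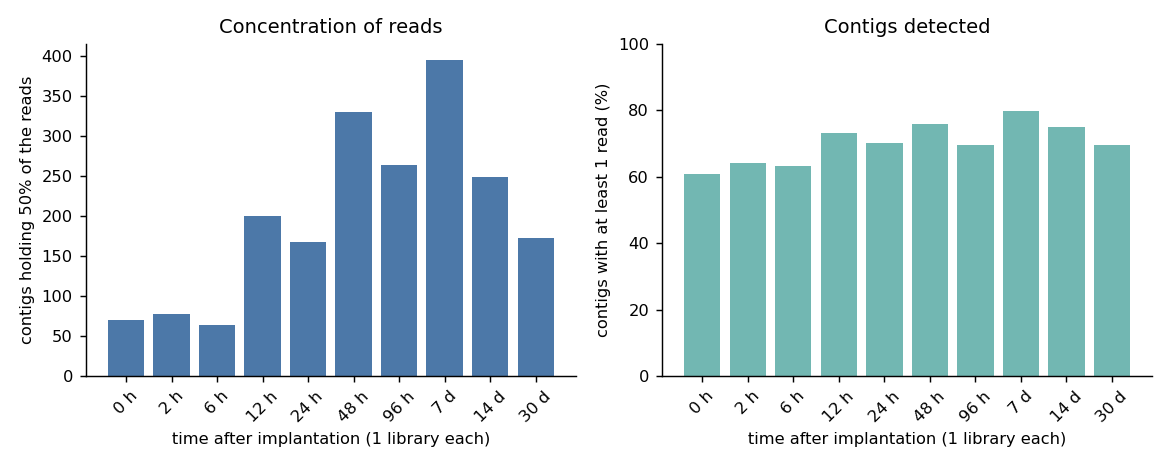
The left panel plots the number of contigs that together hold 50% of the reads and the right panel the percentage of 211508 contigs with at least 1 read, both as bars for each of the 10 libraries in order of time. The number of contigs holding 50% of the reads lies between 64 and 77 from 0 to 6 h, at 395 at 7 d and at 172 at 30 d.

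The second question was how far each library lay from the 0 h library. Over the 52894 kept contigs, Spearman's correlation with the 0 h library was 0.77 at 2 h and 0.83 at 6 h. The lowest values were 0.62 at 12 h and 0.64 at 24 h. From there the correlation was 0.71 at 48 h, 0.76 at 96 h and 7 d, 0.84 at 14 d and 0.85 at 30 d. Neighbouring times were closest to each other from 12 h to 7 d, with 0.89 between 12 and 24 h, 0.88 between 24 and 48 h, 0.92 between 48 and 96 h and 0.92 between 96 h and 7 d. The first 2 principal components held 36.4% and 25.7% of the variance, and under TMM scaling the libraries lay around a ring in order of time, except that 6 h came before 2 h and that 30 d lay just past 0 h. The 30 d library was next to 0 h on this ring (-97.8 against -107 on the first component and -9.82 against -4.79 on the second) and apart from it on the third, which held 10.7% of the variance (78.3 against -48.4). Among the 1000 most variable contigs the order differed: 0.73 at 2 h and 0.72 at 6 h were then above 0.66 at 30 d, and the lowest value was 0.50 at 48 h.

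**Figure D2:**
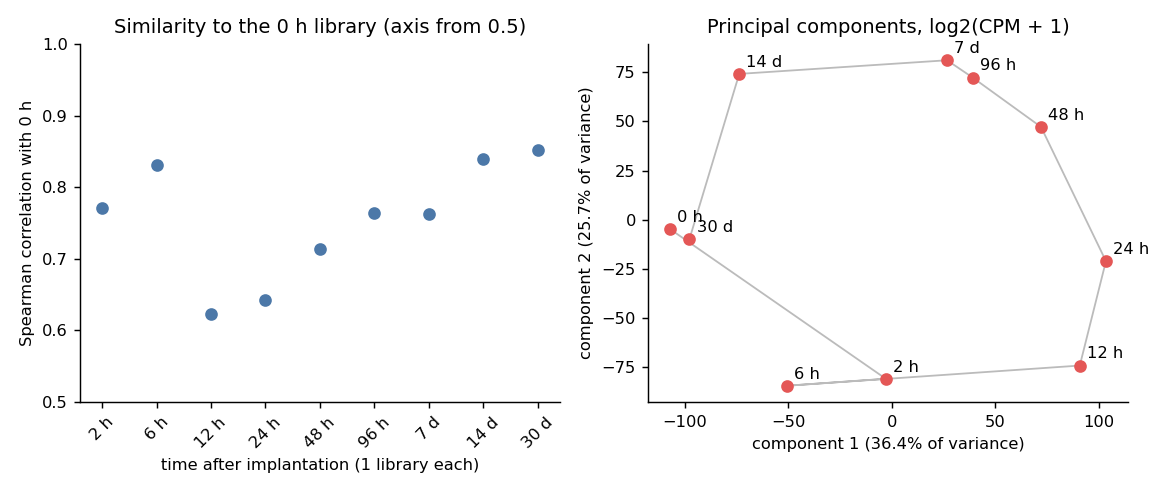
The left panel plots the Spearman correlation of each later library with the 0 h library, on an axis that starts at 0.5, and the right panel the first 2 principal components of log2(CPM + 1) with the libraries joined in order of time. Correlations are lowest at 12 and 24 h (0.62 and 0.64) and highest at 14 and 30 d (0.84 and 0.85), and 30 d lies beside 0 h in the right panel.

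With the prior of 1 CPM, contigs at least 4-fold from their 0 h level were most numerous at 12 and 24 h under TMM scaling, and at 48, 12 and 24 h with total counts. Under TMM at 12 h, 2116 contigs lay at least 4-fold above 0 h and 838 at least 4-fold below, and at 24 h the numbers were 1775 and 1308. At 2 h there were 742 above and 150 below, and at 6 h 894 and 73. From 48 h to 14 d the larger group lay below 0 h under TMM scaling with the prior of 1 CPM: 1368 below against 677 above at 48 h, 1053 against 492 at 96 h, 1105 against 351 at 7 d and 665 against 420 at 14 d. At 30 d, 879 contigs lay above and 159 below. In all, 6593 contigs passed the limit at 1 or more of the 9 later times. This number was 2196 with a prior of 5 CPM in place of 1, 22068 with a prior of 0.1 CPM and 3100 against the mean of the other 9 libraries. Against that mean the order of the times differed: 30 d had the most contigs past the limit, with 960 above and 116 below, while 12 h had 537 and 36 and 24 h 313 and 126. Against 0 h with a prior of 5 CPM, 24 h had the most (535 above and 403 below), and 48 h (225 and 561) passed 12 h (577 and 199). At 14 d the direction turned with a prior of 0.1 CPM (1983 above and 1703 below), and at a 2-fold limit the groups were close in size (2831 above and 2893 below). The direction from 48 h to 14 d also depended on the scaling. With total-count scaling, contigs above 0 h made up 85.0% of those past the limit at 48 h (2780 against 489) and 86.7% at 7 d (2646 against 405), where TMM gave 33.1% and 24.1%. At 12 h they were 91.1% with total counts and 71.6% with TMM, and at 24 h 82.0% and 57.6%. At 96 h and 14 d they were 75.9% and 78.5% with total counts and 31.8% and 38.7% with TMM, while at 30 d they were 96.1% and 84.7%. The median kept contig differed from 0 h by 0.03 on the log2(CPM + 1) scale at 7 d with TMM and by 0.63 with total counts. TMM assumes that most contigs do not change, so its small median follows from the scaling. All 9 comparisons use the same single 0 h library, so any peculiarity of that library is in each of them.

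**Figure D3:**
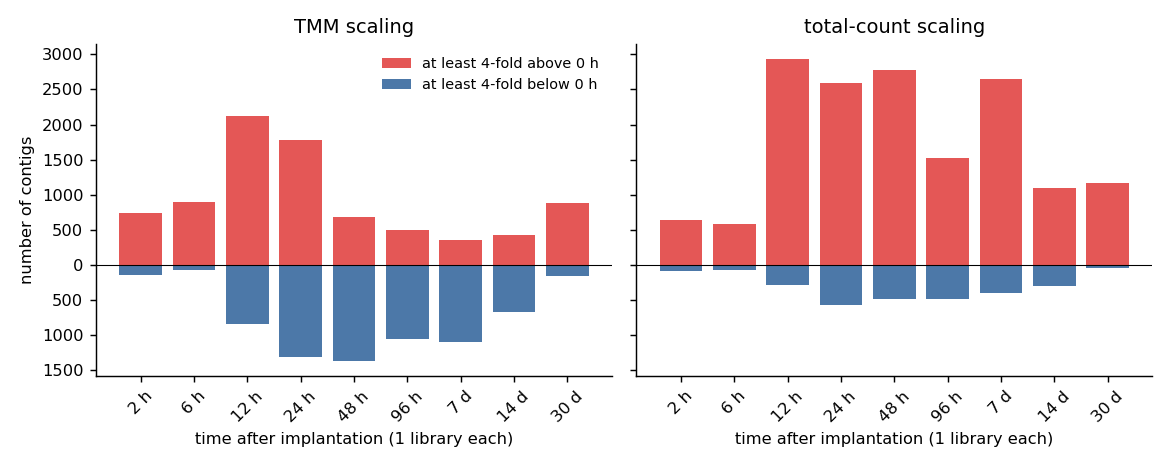
Bars give the number of contigs at least 4-fold above 0 h (red, upward) and below 0 h (blue, downward) in each of the 9 later libraries, with TMM scaling on the left and total-count scaling on the right. With TMM the contigs below 0 h outnumber those above from 48 h (1368 against 677) to 14 d (665 against 420, but 1703 against 1983 with a prior of 0.1 CPM), and with total counts the contigs above are the larger group at every time.

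The 141 most abundant contigs were set against 0 h as a group of their own, here without a prior. At 2 and 6 h none of them lay 4-fold below 0 h, and 8 lay 4-fold above at each time under TMM. Those 4-fold below numbered 5 at 12 h, 20 at 24 h, 53 at 48 h, 52 at 96 h, 57 at 7 d and 54 at 14 d, and 11 at 30 d. With total-count scaling the numbers were 2 at 12 h, 11 at 24 h, 30 at 48 h, 45 at 96 h, 48 at 7 d, 39 at 14 d and 3 at 30 d. Those 4-fold above 0 h numbered 16 at 12 h, 17 at 24 h and 14 at 7 d under TMM, against 19, 19 and 23 with total counts. The median of the group was -1.30 on the log2 scale at 7 d under TMM and -0.03 with total counts. In the test of a smooth change over all times, 13 of the 141 passed, of which 5 had a peak, 4 a trough and 4 a fall.

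A steady change from 0 h to 30 d was asked of each contig with the slope on log2(hours + 1). No contig of 52894 passed in edgeR's quasi-likelihood test (lowest adjusted p = 0.0518), although 4750 had an unadjusted p under 0.05. DESeq2's likelihood ratio test called 609, limma-voom 9 and limma on log2(RPKM + 1) 0. Without the 0 h library edgeR called 692 contigs, without 30 d 528 and without 6 h 2. The contigs with the lowest p of each direction were contig115188 (561 bases) and contig326621 (1402 bases) with a positive slope, and contig035209 (1689 bases) and contig315869 (477 bases) with a negative one. Their CPM values and ratios, and the CPM value of the floor, are given under TMM scaling and without a prior. contig115188 was at 0.06 CPM at 0 h, 0 at 12 and 24 h, 0.27 at 96 h, 0.70 at 7 d, 11.8 at 14 d and 60.2 at 30 d. Its slope was 1.84 ± 0.21 (SE, here and below derived from the F statistic) log2 units per doubling of time. Most of its rise lay at 14 and 30 d, so a straight slope describes it poorly. The 30 d to 0 h ratio was 935 with an exact counting interval (95%) from 167.5 to 36960, since 0 h had 1 read. contig326621 had 0 reads at 0 h and 1.42 CPM at 30 d, which was at least 7.37-fold higher than the floor of 3 reads, 0.193 CPM, while the exact counting interval (95%) of the ratio began at 5.63, with a slope of 0.67 ± 0.09. contig035209 was at 15.7 CPM at 0 h, 9.23 at 12 h, 1.29 at 24 h and 0.28 at 30 d, 55.2-fold lower than at 0 h (25.0 to 152), with a slope of -0.80 ± 0.11. contig315869 was at 42.5 CPM at 0 h, 9.92 at 6 h, 0.88 at 48 h and 0.81 at 30 d, 52.7-fold lower (32.7 to 91.0), with a slope of -0.72 ± 0.10. All 4 also passed the joint test of a smooth change, which contains the slope they were chosen by and adds no independent support, with edgeR adjusted p = 0.000103, adjusted p = 0.00531, adjusted p = 0.00455 and adjusted p = 0.00431 in the order named.

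A smooth change of any form was asked with a curve that has a linear and a quadratic term, tested jointly, so that a pass does not by itself show a turn. In edgeR's quasi-likelihood test 3420 of 52894 contigs (6.47%) passed. Under TMM scaling, the fitted curve had a peak in 1344 of the 3420, a trough in 1856, a rise in 68 and a fall in 152, while total counts gave more peaks (4413) than troughs (2583). The contigs with a peak were at a median of 1.77 log2 units above 0 h at 12 h and 1.65 at 24 h, then 1.25 at 48 h, 0.74 at 7 d and 0.04 at 30 d, and 592 had their highest library at 12 h and 408 at 24 h. The contigs with a trough were at a median of -0.97 at 12 h, -1.17 at 48 h, -0.80 at 7 d and -0.14 at 14 d. At 30 d their median was 0.73 above 0 h, and 1139 of the 1856 had their highest library there. The rising contigs were at a median of 0.55 at 96 h, 1.39 at 14 d and 1.25 at 30 d, and the falling ones at 0.02 at 6 h, -0.71 at 12 h, -1.34 at 48 h and -1.42 at 30 d. These medians are on the log2(CPM + 1) scale and belong to contigs picked by the test, which favours large values. The fitted turning point had a median of 24.4 h for peaks and 20.6 h for troughs, and 21 peaks and 145 troughs had theirs after 96 h. The turning point itself was not tested, and the shape rule bounds it between 2 h and 14 d. Troughs had their lowest library most often at 48 h (542 contigs) and 24 h (498), later than their fitted median. A value in a single library can pass the test: of 55 contigs with at least 10 CPM at 30 d and under 1 CPM at every other time, 22 were tested and 18 passed. By abundance, 5.30% of contigs with a mean under 1 CPM passed, 7.11% of those at 1 to 10, 7.51% at 10 to 100 and 9.29% at 100 to 1000. Contigs that passed had a median length of 1426 bases, against 1118 for the others.

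The number with a smooth change depended on single libraries and on the scaling. It was 7677 without 6 h, 5814 without 30 d, 4867 without 0 h, 2180 without 7 d, 2101 without 14 d, 2032 without 2 h, 1770 without 96 h, 1590 without 12 h, 1585 without 48 h and 858 without 24 h. Of the 3420 contigs, 843 were called again without 24 h and 3398 without 6 h. With TMM 1995 of the 3420 curves (58.3%) opened upward, as a trough does. With total-count scaling 7869 contigs passed, 39.9% opened upward, and there were 4413 peaks, 2583 troughs, 778 rises and 95 falls. Without 30 d 38.3% opened upward, with 3005 peaks and 1694 troughs, and without 6 h 49.6%, with 3758 and 3624. Over the left-out times peaks numbered 284 (without 24 h) to 3758, and troughs 526 (without 24 h) to 3624. Rises numbered 14 without 24 h, 236 without 0 h and 255 without 30 d, and falls 34 without 24 h, 766 without 0 h and 860 without 30 d. The limits of the shape rule moved with the times left in. They were 6 h and 14 d without 0 h or 2 h, and 2 h and 7 d without 14 d or 30 d. Shape counts of those fits therefore differ partly by definition. DESeq2 called 9547 contigs and limma on log2(RPKM + 1) 2069, while edgeR called 21910 with no filter, 5311 on the rank of time and 378 among the 11376 contigs with at least 5 CPM in 5 libraries.

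**Figure D4:**
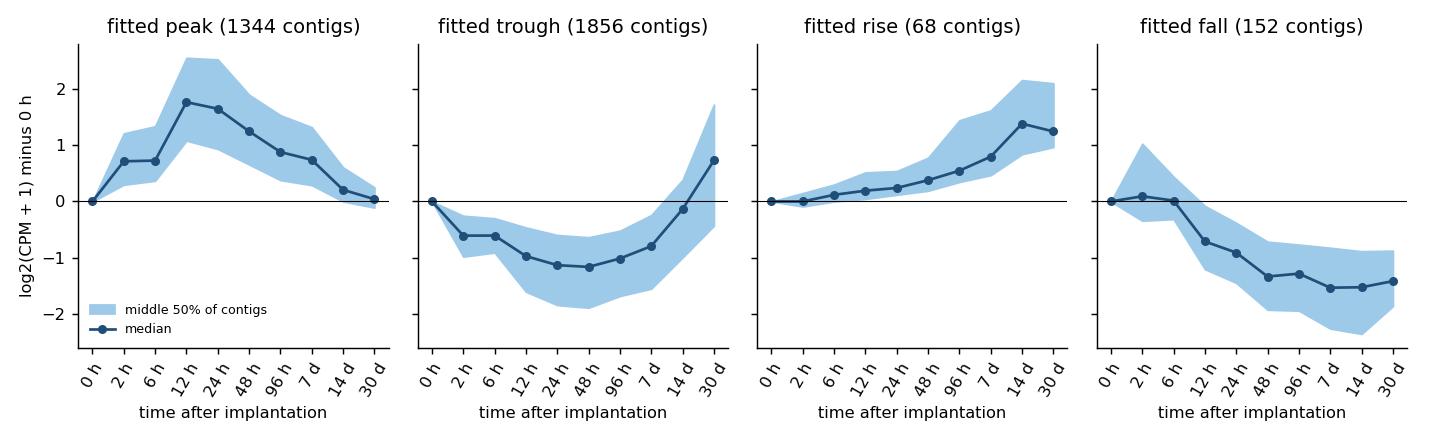
Each panel plots, for the contigs with a smooth change whose fitted curve has that shape, the median (line and points) and the middle 50% of contigs (band) of log2(CPM + 1) minus the 0 h value, under TMM scaling over the 10 times with 1 library each; total counts gave 4413 peaks and 2583 troughs. The peak group is highest at 12 h (median 1.77) and near 0 h again at 30 d (0.04), and the trough group is lowest at 48 h (-1.17) and above 0 h at 30 d (0.73).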

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

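One signal lay in data that the comparisons did not use. The contigs that could not be read at 30 d summed to 979.6 CPM at 14 d, against 541 at 0 h, a ratio of 1.81 with total counts and of 1.05 under TMM scaling. In the other 7 libraries that could be read there the sum lay between 339 CPM at 96 h and 564 at 7 d. At 30 d the same contigs held 22413 reads by the RPKM total, or 1054 CPM, so 14 d did not stand alone. No group had more than 1 library, so no library could be compared with others of its group and no difference of effects between groups could be tested.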

How the results depend on the processing

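Total-count scaling of the tests, equal depth, minima of 3 and 10 reads, a mean of at least 5 CPM and leaving out the 1000 most abundant contigs were chosen after seeing the data. Gene list tests and their alternatives were not run because the files do not pair contigs with names, nor were alternatives meant for files without counts, and no replicate exists to leave out, so each time was left out in turn. The slope count of 0 was 3686 with no filter, 609 with DESeq2, 20 with total counts, 9 with limma-voom and 1 with the rank of time, 0 in the other 3 settings, and 0 to 692 over the left-out times. The 4 named slopes kept their direction in every setting that gave a value, and 24 of 67 such values passed the threshold. These settings refit the libraries by which the 4 were picked, so they add no independent support. The smooth-change count of 3420 was 21910 with no filter, 9547 with DESeq2, 7869 with total counts, 5311 with the rank of time, 2069 on log2(RPKM + 1) and 378 with at least 5 CPM in 5 libraries (11376 contigs tested), and 858 to 7677 over the left-out times; DESeq2 size factors (3562) and limma-voom (2904) stayed within 1.5 times. The share of curves opening upward, 58.3%, turned to a minority with no filter (48.2%), the 5 CPM filter (49.5%) and total counts (39.9%), and ran from 38.3% (without 30 d) to 71.1% (without 12 h), with 49.6% without 6 h. Contigs at least 4-fold from 0 h at any time, 6593, numbered 22068 with a prior of 0.1 CPM, 2196 with a prior of 5 CPM, 26206 at a 2-fold limit and 3100 against the mean of the other 9 libraries. The correlation with 0 h was higher at 30 d than at 12 h by 0.229, and by 0.106 over the 1000 most variable contigs, 0.303 at a mean of at least 5 CPM and 0.242 without the 1000 most abundant contigs. The 7 d excess of 40513 detected contigs over 0 h was 42310 at equal depth, 33386 at 3 reads, 17001 at 10 reads and 14228 without the 1000 most abundant contigs and with every library reduced to 4017330 remaining reads. The cause of these changes was not tested. Depth limits contigs under 1 CPM most, since the fewest reads stand behind their values.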

Other observations

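The tests of library depth and of a wrong 0 h label were chosen after the result was seen, and the limit for the comparison with other orders of the libraries was written down after their counts were seen. The settings without the 1000 most abundant contigs and with a mean of at least 5 CPM were added after seeing the data, before these tests were run.

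A set of contigs stood out by being found in 1 library. Of 65 contigs with at least 10 CPM in 1 library and under 1 in each of the others, 55 were in the 30 d library, 3 each at 0 and 24 h and 2 each at 2 and 48 h. The 55 held 140352 reads, 0.660% of the 30 d library, of which 62.1% lay in a single contig, and their median was 302 reads. Of the 55, 1.82% lay within 1000 contig numbers of the unreadable part of the 30 d file, which argues against damage close to that part as their source. Damage elsewhere in the file was not tested. Transcripts that start late in sac formation, transcripts carried by the mussels of that library alone and reads of another organism may each account for the set, and none of these could be tested without names or sequences.

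More contigs had reads at 7 d than at 0 h. Library depth is argued against, because the 7 d library held 95.5% as many reads as the 0 h library. Sequences of the 7 d library alone were checked in the 189 contigs with no reads from 0 to 6 h and at least 10 at 7 d. Of these 189, 66.7% had at least 3 reads in at least 2 of 6 other libraries, which argues against that explanation for this set. The 189 held 0.0147% of the 7 d reads and the excess at 7 d was 40513 contigs, so the check cannot decide it for the contigs with fewer reads. A few contigs taking most of the reads may account for part of the difference, since 35.1% of it was left without the 1000 most abundant contigs at equal remaining reads. There 122273 contigs had reads at 0 h, 132919 at 6 h, 135663 at 12 h, 136501 at 7 d and 134179 at 14 d, but 125136 at 24 h and 125143 at 96 h. What was left was therefore not particular to 7 d. A broader mixture of cells in the growing sac, or a broader program in the same cells, stays open for the rest and was not tested.

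The libraries of 14 and 30 d were nearer to 0 h than that of 12 h. Noise of low counts is argued against by a difference of 0.303 among contigs with a mean of at least 5 CPM. A wrong label on the 0 h library stays open: the 6 h library was nearer to 14 and 30 d than to 24 h to 7 d by 0.053, but for the 2 h library this difference was -0.060. A return toward the state of the 0 h library is a hypothesis, and it cannot be separated from differences between mussels with 1 library per time.

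The smooth-change count was compared with other splits of the libraries over the time axis. Of 100 orders, 1, the real one, gave as many as 3420 contigs. The highest of the 99 others gave 2948, the next 575, and 77 gave 0. A share of 1 in 100 is the lowest that 99 other orders can give, and the limit for it was set after the counts were seen. It argues against chance in this setting without excluding it. No other setting was run on the other orders, the left-out times moved the real count from 858 to 7677, and the order does not separate time from whatever else changed with it.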
